A study of Homo sapiens with 8 samples.

How the data were processed

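Bulk RNA sequencing of the H9 cell line and its kidney organoids was analysed from a table of 58676 genes and 14 numbered columns. Per the labels' protocols, RNA was extracted with TRIzol from pooled organoids and libraries were made with the NEBNext Ultra kit. Per the submitters' processing notes, STAR, HTSeq, DESeq2 and edgeR were used, with no role stated, and their versions and the genome build are not given in the sources used here. Whether reads were counted by strand is not given either, so values of overlapping or antisense genes are uncertain. The deposited values are FPKM in 13 columns, scaled by the authors to each column's own total of reads assigned to genes. PSC column 3 holds the authors' raw counts instead, with a total of 15496383. A second sheet holds the authors' mean FPKM per stage. The units were read from the values, since no header states them.

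The FPKM of PSC column 3 was worked back from the authors' PSC mean and the other PSC columns. The gene lengths this implies were whole numbers, within 0.01, for all 28818 genes counted in that column, and 26099 of them equalled the exon length in GENCODE v29. With these lengths, the reads of the same genes in the other columns came out whole within 0.01. For 14347 further genes the length from GENCODE v29 was taken because it made their reads whole, so for these wholeness is no check. A further 1142 genes were given the smallest length that makes their reads whole, which is a guess, and 17 had no length. The total of assigned reads this implies per library was between 11501039 and 18910894. All 58676 gene identifiers are in GENCODE v29 of GRCh38, from which positions were taken. Counting error is small for abundant genes, and genes near 1 FPKM rest on few reads.

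The series lists 1 sample per stage and the table gives numbered columns for each. The columns were treated as separate libraries because columns of 1 stage differed by more than sampling noise, which excludes only that a single library was counted again. They may still be repeat libraries of 1 sample, in which case the p-values are too small for a comparison of cultures. The organoid columns name no culture system and were matched by title to the samples described as static, so the organoids are called by day only. The 3 suspension samples were not analysed here.

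The main test was limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(FPKM + 1), on genes with at least 1 FPKM in as many libraries as the smallest stage in the fit, with Benjamini-Hochberg adjustment at 0.05. The NPC and PSC comparison used those 6 libraries, organoids against NPC 11, and the organoid days 8. A set of 45 gene lists was tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, for lists with at least 3 tested members. Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, median-of-ratios scaling, a robust fit, day as a linear term and leaving out each library. Further alternatives were added after the table was seen: edgeR 4.0.16, DESeq2 1.42.0 and limma-voom on the reads worked back, the column number as a block, all 14 columns in one fit, and the raw counts of PSC column 3 taken as FPKM. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

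The groups, gene lists, named-gene rule and the first set of other settings were fixed before the data were examined. The rule took, for day 49 against day 21, the 15 largest rises and 15 largest falls past the threshold with a mean of at least 5 FPKM. For the stage comparisons it took 10 each way with at least 10 FPKM in a stage, and 10 each way for day 35 against day 21. Libraries of the groups could not overlap, and histone genes, clone names, Y-linked genes and the X-inactivation RNAs were left out. List members were added as examples. The plan had assumed counts, both culture systems and 1 library per stage, with no test for NPC against PSC or organoids against NPC. With FPKM and numbered columns, limma replaced edgeR, these comparisons were tested, CPM in the rule was read as FPKM, non-overlap and the threshold were added to the stage rule, more name prefixes were left out, and day 49 against day 35 was added.

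The gene tests of 4 comparisons were run on simulated data, with 50 genes changed at each of 4 fold sizes, and day 49 against day 35 and the list tests were not. At 2-fold, 98% were recovered for NPC against PSC over 15579 genes, 94% for organoids against NPC over 19270, 94% for day 35 against day 21 over 18613 and 80% for day 49 against day 21 over 18568. At 1.5-fold these were 40%, 70%, 64% and 64%, at 3-fold 88%, 96%, 90% and 88%, and at 4-fold 94%, 98%, 98% and 92%. The share of false calls was 8%, 3.8%, 3.9% and 1.8%, so that of the first comparison lay above the nominal level. The changed genes were drawn from those above a floor in mean FPKM, so recovery of the lowest genes was not measured. Few genes were changed in the simulation, up and down equally often. In the data 6823 and 4812 of 15981 genes were called for NPC against PSC, so these shares do not measure the error of the real calls.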

Results

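Gene expression was measured by RNA sequencing along the differentiation of the human embryonic stem cell line H9 into kidney organoids, which are cell aggregates that form nephron-like structures in culture. The stages were pluripotent stem cells (PSC, day 0), the nephron progenitor stage (NPC, day 8), and organoids at days 21, 35 and 49. The series holds 8 samples, and its stated aim is to follow expression over time and under static and suspension culture. The deposited table has 14 numbered columns, matched here to 5 of these samples: 3 each for PSC, NPC, day 21 and day 35, and 2 for day 49. No column could be tied to the 3 samples of suspension culture, which were not analysed here, so the culture systems were not compared. The organoid columns do not name a culture system. They were matched to the samples of days 21, 35 and 49 whose titles, like the columns, have no word for suspension.

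The columns are called libraries below. Each stage is 1 sample in the series, and nothing states whether its columns came from separate cultures, so every SD, SE and p-value measures only the spread between these columns, which may be technical. Columns of 1 stage differed from each other by 2.40 to 8.28 times the sampling noise of their reads (chi-square per gene), so they are not a single library counted again. The reads assigned to genes ranged from 11501039 in a day 35 library to 18910894 in an NPC library. Values are FPKM (fragments scaled to transcript length and to the reads of the library), given as mean ± SD with n = 3 libraries, or n = 2 at day 49. Changes are limma estimates on log2(FPKM + 1) with their SE, which understate the change of low genes. Every adjusted p is from limma or, for gene lists, camera unless fry is named, with Benjamini-Hochberg adjustment. Unless the full list size is given, counts of list genes are out of the tested members only. Many lists have further members that did not reach the filter.

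The first comparison asks what changes from PSC to NPC. Most genes of the pluripotency list fell by day 8, some to near 0 and others in part. POU5F1 (ENSG00000204531, chromosome 6, 31164337 to 31180731 in GRCh38, GENCODE v29, matched here by gene identifier), the transcription factor OCT4, fell from 385 ± 53.4 to 0.116 ± 0.0365 FPKM, a log2 change of -8.43 ± 0.10 (adjusted p = 8.61e-09). SOX2, another factor of the pluripotency network, fell from 211 ± 9.76 to 2.41 ± 0.40 FPKM, and PRDM14 from 56.7 ± 5.45 to 0.00884 ± 0.0153 FPKM. Of 22 measured members of the pluripotency list, 21 fell and 1, LIN28B, did not pass. LIN28A remained at 208 ± 9.27 FPKM, from 829 ± 30.6 in PSC. The list was lower by camera (adjusted p = 7.07e-13; adjusted p = 0.0745 with an estimated correlation). The long RNA ESRG fell from 196 ± 5.41 to 0.00561 ± 0.00972 FPKM, and OTX2, NPTX1 and L1TD1 were also among the 10 largest falls.

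Genes of the nephron progenitor rose. WT1 went from 0 in all 3 PSC libraries to 37.0 ± 5.44 FPKM, with a log2 change of 5.24 ± 0.10 (adjusted p = 6.54e-08). PAX8 rose to 19 ± 1.89 and EYA1 to 25.3 ± 1.52 FPKM. Of 17 measured members of this list 16 rose and 1 fell (camera adjusted p = 2.5e-06; adjusted p = 0.161 with an estimated correlation). HOX genes, which record position along the body axis, rose without exception among those tested: 15 of 15 in groups 1 to 5 and 12 of 12 in groups 6 to 9. HOXB9 rose from 0.0578 ± 0.0133 to 444 ± 19.8 FPKM (log2 change 8.72 ± 0.05, adjusted p = 1.35e-09). HOXB8 reached 94.9 ± 6.44 and HOXA5 92.9 ± 1.41 FPKM, from 0 in each PSC library. Both HOX lists passed camera with adjusted p = 3.52e-08 and 2.9e-08, and each had an adjusted p = 0.105 with an estimated correlation. The loci MIR10B and MIR196A1 and the RNA HOXB-AS3 were among the largest rises too, but they lie in HOX clusters, where reads of overlapping or opposite transcripts may be counted for them.

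Mesenchymal genes rose while epithelial genes fell. Of 21 measured stromal genes 19 rose and 2 fell, with TWIST1, a driver of mesenchymal state, going from 0.147 ± 0.0374 to 56.9 ± 3.94 FPKM (log2 change 5.66 ± 0.07). The collagen gene COL3A1 rose from 0.329 ± 0.0564 to 36.5 ± 4.63 FPKM. The stromal list had an adjusted p = 2.93e-06 by camera, and an adjusted p = 0.0902 with an estimated correlation. Of 23 general epithelial genes 22 fell and 1, PAX8, rose. CDH1, the E-cadherin gene, fell from 62.4 ± 3.1 to 0.0523 ± 0.0206 FPKM, and the tight junction gene CLDN6 from 303 ± 25.9 to 4.41 ± 0.739 FPKM (list adjusted p = 6.23e-12 by camera; adjusted p = 0.0745 with an estimated correlation). Of 19 primitive streak and early mesoderm genes 9 were tested. All 9 rose, among them CDX1 (10.2 ± 1.43 FPKM at NPC) and MSGN1 (2.58 ± 0.528 FPKM). The list had camera adjusted p = 0.000944, and adjusted p = 0.151 with an estimated correlation. In every list of this comparison, a gene below 1 FPKM in all PSC libraries was tested only if the NPC libraries reached 1 FPKM. Such genes could mainly rise. The imprinted genes H19 and IGF2 rose to 1140 ± 18.6 and 205 ± 54.6 FPKM, from 0.968 ± 0.158 and 0.0103 ± 0.0104 FPKM.

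Metabolic and growth genes moved in smaller steps. Of 25 cholesterol synthesis genes 22 fell and 3 did not pass (list adjusted p = 1.36e-08 by camera; adjusted p = 0.105 with an estimated correlation). Of 38 cell cycle genes 24 fell and 7 rose (camera adjusted p = 0.000624; adjusted p = 0.455 with an estimated correlation). The replication helicase genes MCM5 and MCM4 fell by 1.52 and 1.5 on the log2 scale. In the metallothionein and oxidative stress list 15 of 18 genes fell, with MT1G at 9.04 ± 4.83 in PSC and 0.0295 ± 0.051 FPKM at NPC (camera adjusted p = 0.000156; adjusted p = 0.105 with an estimated correlation). Metallothionein genes are near-identical copies, so their reads may be shared. For each list named here, the count adjusted over the list alone was the same. No list of this comparison passed with an estimated correlation.

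Over all 15981 genes tested, 6823 were higher and 4812 lower at NPC than at PSC, of which 2178 and 1484 changed at least 2-fold on the log2(FPKM + 1) scale. The median change of all genes was 0.16, and median-of-ratios scaling moved it to -0.02. With that scaling 5255 genes were higher and 6103 lower, so the larger number of rises depends on the scaling.

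The next comparison asks what the organoids, averaged over days 21, 35 and 49, express beyond the NPC stage. Podocyte genes rose almost without exception: 31 of 33 measured members rose and 2 fell (camera adjusted p = 3.42e-15; adjusted p = 0.0381 with an estimated correlation). NPHS1 (ENSG00000161270, chromosome 19, 35825964 to 35869287), the nephrin gene, went from 0.194 ± 0.0569 at NPC to 78.5 ± 1.63 FPKM at day 21 (log2 change of the organoid mean 5.52 ± 0.06, adjusted p = 1.54e-12). PODXL, which coats podocyte foot processes and is also abundant in PSC, stood at 282 ± 9.02 in PSC, 2.01 ± 0.148 at NPC and 340 ± 16.2 FPKM at day 21. Of 54 proximal tubule genes 32 were tested, of which 29 rose and 1 fell (camera adjusted p = 5.55e-12, and adjusted p = 0.0101 with an estimated correlation). The glucuronidation enzyme UGT2B7 and the endocytic receptor CUBN were among those that rose, at 8.82 ± 0.482 and 8.77 ± 1.62 FPKM at day 21.

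Genes of more distal segments rose too. Of 17 loop of Henle genes 15 rose (camera adjusted p = 3.64e-05; adjusted p = 0.115 with an estimated correlation), led by the transcription factor POU3F3 at 29.8 ± 0.777 FPKM on day 21. Of 30 collecting duct and ureteric genes 10 were tested, of which 9 rose and 1 did not pass (camera adjusted p = 0.000139, and adjusted p = 0.0362 with an estimated correlation). The largest of these rises, GATA2, reached 14.0 ± 2.02 FPKM at day 49. The mean log2(FPKM + 1) over 14 genes of this list was 1.141 to 1.179 in PSC, 0.422 to 0.425 at NPC and 1.235 to 1.291 at day 21. By day 21 the mean of the list was thus only a little above its PSC level. Whether the same genes made up the mean at both stages was not tested. In every list of this comparison, a gene below 1 FPKM in all NPC libraries was tested only if organoid libraries reached 1 FPKM. Such genes could mainly rise. General epithelial genes returned, with 23 of 26 higher than at NPC: CDH16, a kidney cadherin, rose from 0.0166 ± 0.0178 to 40.1 ± 0.986 FPKM at day 49 (camera adjusted p = 6.47e-12; adjusted p = 0.0362 with an estimated correlation). The angiotensin receptor gene AGTR2 rose from 1.37 ± 0.159 at NPC to 60.2 ± 11.1 FPKM at day 49. Of 20 endothelial genes 15 rose and 3 fell. CLDN5 rose to 26.4 ± 1.00 FPKM at day 21, whereas KDR, the main VEGF receptor gene, fell from 21.0 ± 1.65 to 3.46 ± 0.131 FPKM at day 21 (camera adjusted p = 0.00268; adjusted p = 0.238 with an estimated correlation).

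Skeletal muscle genes had the largest median change among the lists tested in this comparison. All 31 measured members rose, with a median log2 change of 4.35 (camera adjusted p = 1.64e-19; adjusted p = 0.0883 with an estimated correlation). MYH3 (ENSG00000109063, chromosome 17, 10628526 to 10657309), the embryonic myosin heavy chain, went from 0.777 ± 0.136 at NPC to 460 ± 3.27 FPKM at day 21, and the alpha-actin gene ACTA1 from 1.12 ± 0.47 to 573 ± 16.5 FPKM. MYOG, a transcription factor of muscle differentiation, rose from 0.253 ± 0.147 to 125 ± 6.01 FPKM. MYLPF, MYL1, MYBPH and TNNC2 were also among the 10 largest rises of the comparison. The summed FPKM of the list was between 40.6 and 42.3 in the NPC libraries and between 849 and 3634 in the 8 organoid libraries.

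Stromal genes continued to rise (24 of 32; camera adjusted p = 6.2e-07; adjusted p = 0.0231 with an estimated correlation), with OGN at 47.6 ± 2.55 and POSTN at 84.1 ± 6.34 FPKM on day 21. Proliferation genes fell: 37 of 39 cell cycle genes were lower and 2 did not pass (camera adjusted p = 2.23e-18; adjusted p = 0.0362 with an estimated correlation), and CENPF fell from 69.5 ± 9.19 to 11.4 ± 0.345 FPKM at day 21. HOX genes of groups 1 to 5 fell in 14 of 15 cases (camera adjusted p = 1.72e-07; adjusted p = 0.0231 with an estimated correlation), and those of groups 6 to 9 in 10 of 12 (camera adjusted p = 2.52e-05; adjusted p = 0.0252 with an estimated correlation). HOXB9 went from 444 ± 19.8 to 30.7 ± 2.91 FPKM at day 21. In groups 10 to 13 the 4 measured genes rose instead, although that list did not pass (camera adjusted p = 0.0589). The largest fall was that of LIN28A, an RNA-binding protein gene of early embryonic cells, from 208 ± 9.27 to 0.32 ± 0.102 FPKM at day 21 (log2 change of the organoid mean -7.51 ± 0.06, adjusted p = 4.02e-13). Nephron progenitor genes were mixed: 10 rose and 10 fell, with EYA1 lower (2.87 ± 0.335 FPKM at day 21) and PAX2 higher (29.8 ± 1.11 FPKM at day 21). The list did not pass by camera (adjusted p = 0.427), which sets it against the other genes, and passed by fry (adjusted p = 1.07e-05, mean log2 change -0.485), which does not.

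Of 20195 genes tested, 6009 were higher and 5818 lower in organoids than at NPC, of which 1864 and 927 changed at least 2-fold. Adjusted over the list alone, 30 proximal tubule genes were higher and 6 stromal genes lower, in place of 29 and 5, and the other lists named for this comparison kept their counts.

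**Figure D1:**
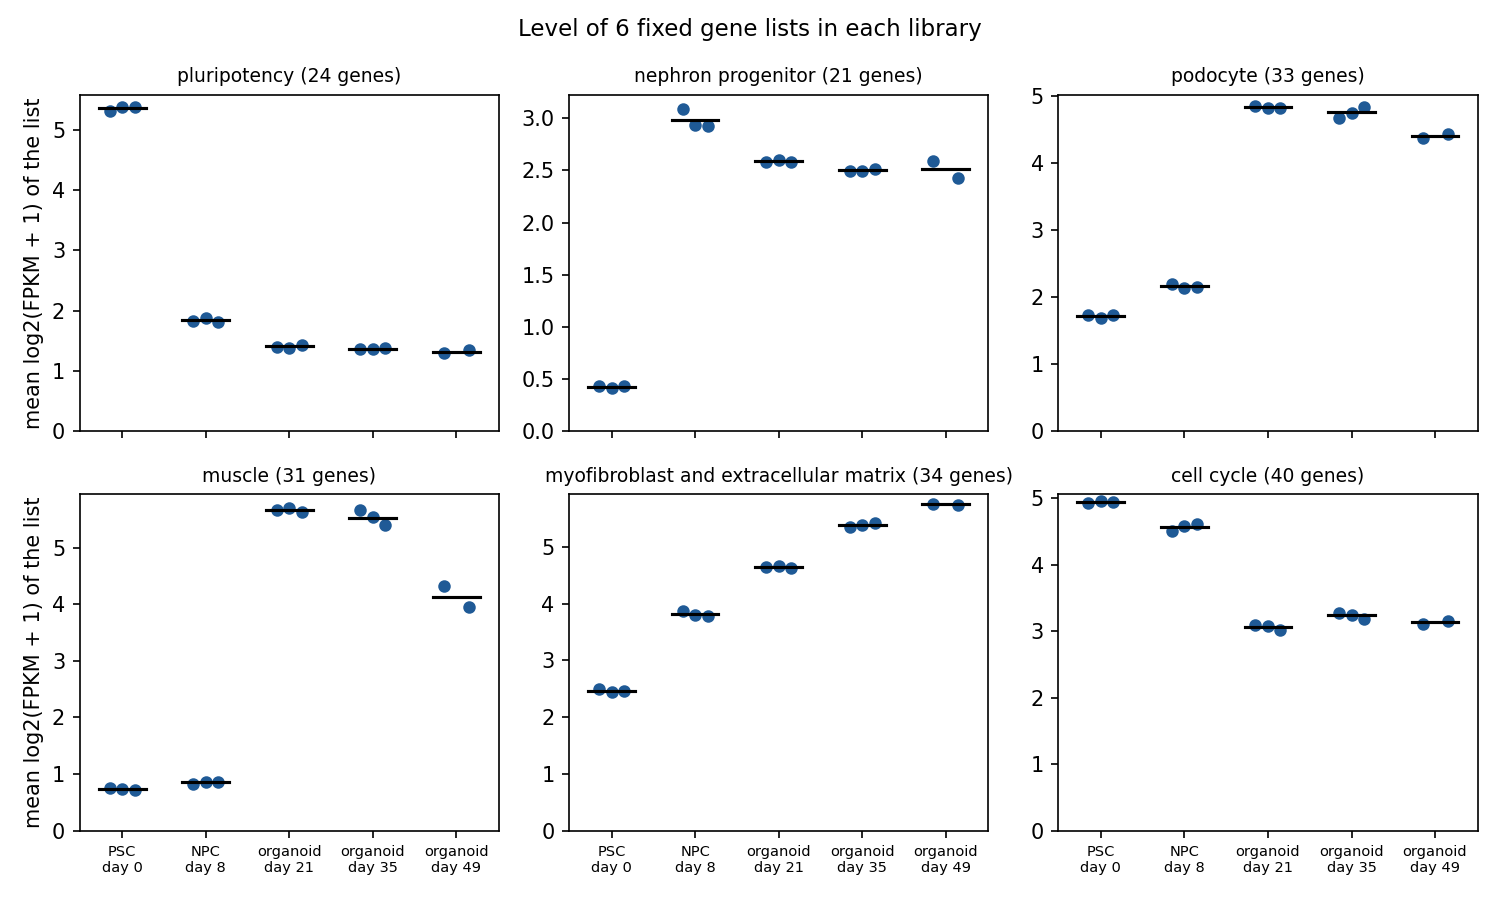
The vertical axes give the mean log2(FPKM + 1) over the genes of 6 lists, and the horizontal axes the 5 stages; points are the 14 libraries and lines the stage means. The pluripotency list drops between PSC and NPC, and the muscle and podocyte lists are highest at days 21 and 35.

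The remaining comparisons follow the organoids from day 21 to days 35 and 49. Extracellular matrix and stromal genes rose. ELN (ENSG00000049540, chromosome 7, 74027789 to 74069907), the elastin gene, went from 1.88 ± 0.152 at day 21 to 47.4 ± 1.31 at day 35 and 119 ± 11.2 FPKM at day 49, a log2 change of 5.38 ± 0.07 from day 21 to day 49 (adjusted p = 2.18e-08). COL1A1 went from 178 ± 6.87 to 974 ± 9.41 and 1990 ± 187 FPKM, and COL3A1 from 341 ± 7.81 to 1188 ± 8.59 and 1944 ± 56.1 FPKM. ACTA2, the smooth muscle actin of myofibroblasts, went from 1.58 ± 0.558 to 63.3 ± 1.06 FPKM at day 49. Between days 21 and 49, 23 of 32 matrix genes rose and 3 fell, and 23 of 32 stromal genes rose and 5 fell. Each list had camera adjusted p = 7.6e-12, and adjusted p = 0.099 and 0.146 with an estimated correlation. The same counts adjusted over the list alone were 23 and 24 genes higher. Further large rises were those of the matrix protease gene MMP7, PI15, SPARCL1, ITM2A, COL15A1, NFIX, INHBA, MGP, THBS2, LUM, PRSS35 and SRPX.

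Muscle genes fell from day 21 to day 49. Of 31 members 30 fell and 1 rose, with a median log2 change of -1.57 (camera adjusted p = 3.1e-14; adjusted p = 0.326 with an estimated correlation). MYH8, the perinatal myosin heavy chain, went from 146 ± 6.88 to 64.5 ± 13 and 15.8 ± 3.66 FPKM, and MYH3 from 460 ± 3.27 to 352 ± 60.3 and 105 ± 25.4 FPKM. MYOG stood at 125 ± 6.01, 190 ± 11.2 and 95.3 ± 17.6 FPKM. Between days 35 and 49, 29 of 31 members fell, and between days 21 and 35, 6 rose and 8 fell (9 adjusted over the list alone). MSTN, which encodes myostatin, an inhibitor of muscle growth, had the largest fall among the named genes, from 18.9 ± 1.35 to 0.748 ± 0.0625 FPKM (log2 change -3.51 ± 0.09, adjusted p = 3.5e-07). MYBPC1, CASQ2, MYL1 and MYOM1 were among the 15 largest falls. So was ACTN3, which is not in the muscle list and took another course, with 40.8 ± 6.47 FPKM at NPC, 12.1 ± 0.594 at day 21 and 0.831 ± 0.121 at day 35. Also among these 15 falls were ECEL1, IGDCC3, ACTA1, IL17B, GJD2, C20orf166-AS1, SHISA3 and EPHA3.

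Most podocyte genes fell over the same time. Of 33 measured members 23 were lower at day 49, 6 higher and 4 did not pass (camera adjusted p = 0.000362; adjusted p = 0.38 with an estimated correlation). NPHS1 went from 78.5 ± 1.63 to 60.6 ± 3.88 and 32.6 ± 4.00 FPKM (log2 change -1.25 ± 0.08, adjusted p = 2.42e-05), and PODXL from 340 ± 16.2 to 261 ± 24.9 and 143 ± 7.1 FPKM. Adjusted over the list alone, 23 were lower and 7 higher. The transcription factor WT1 fell from 73.7 ± 2.92 to 31.6 ± 1.63 FPKM. The members that rose included COL4A4 and COL4A3, chains of the mature glomerular basement membrane, which went from 1.89 ± 0.0824 to 11.5 ± 1.20 and from 0.783 ± 0.0902 to 6.47 ± 1.15 FPKM. Over the same days the summed FPKM of the muscle list went from between 3407 and 3634 to between 849 and 1199 per library, and that of the matrix list from between 2057 and 2130 to between 6982 and 7487.

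Tubule genes were mixed. Of 32 proximal tubule genes 9 rose, 14 fell and 9 did not pass between days 21 and 49, with a median log2 change of 0.01 (camera adjusted p = 0.909). The phosphate transporter gene SLC34A1 went from 8.72 ± 0.62 to 0.268 ± 0.193 FPKM, whereas UGT2B7 went from 8.82 ± 0.482 to 20.3 ± 0.0355 and BHMT from 1.55 ± 0.0896 to 13.1 ± 1.17 FPKM. Of 17 loop of Henle genes 12 fell and 3 rose, with SLC12A1, the sodium-potassium-chloride cotransporter, going from 3.13 ± 0.537 to 0.102 ± 0.00165 FPKM (camera adjusted p = 0.00533; adjusted p = 0.38 with an estimated correlation). Of 35 drug transporter and metabolism genes 17 were tested, of which 11 rose and 2 fell (camera adjusted p = 1.48e-05, and adjusted p = 0.22 with an estimated correlation). The efflux pump gene ABCB1 rose from 0.653 ± 0.142 to 4.07 ± 0.293 FPKM. In the endothelial list 6 genes rose and 7 fell. CLDN5 fell from 26.4 ± 1.00 to 7.93 ± 1.30 FPKM and CD34 rose from 0.926 ± 0.0813 to 2.54 ± 0.278 FPKM (camera adjusted p = 0.672). Adjusted over the list alone, 12 drug transporter genes were higher and 8 endothelial genes lower, and the tubule lists kept their counts.

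Glycolytic genes fell, 16 of 19 by day 49, with 1 higher (camera adjusted p = 2.15e-06; adjusted p = 0.352 with an estimated correlation). The glucose transporter gene SLC2A1 went from 166 ± 20 to 102 ± 3.7 and 57.5 ± 14.0 FPKM, and the enolase gene ENO1 from 1119 ± 61.6 to 618 ± 23.6 and 540 ± 79.7 FPKM. At day 35, 15 of 19 were lower than at day 21 (16 adjusted over the list alone). Of 32 hypoxia genes 18 fell and 4 rose (camera adjusted p = 0.00732; adjusted p = 0.448 with an estimated correlation). Of 25 cholesterol synthesis genes 16 fell and 1 rose (camera adjusted p = 0.00318; adjusted p = 0.326 with an estimated correlation). Of 17 Notch pathway genes 10 fell and 2 rose, with HEY1 from 13.4 ± 0.694 to 4.76 ± 0.113 FPKM (camera adjusted p = 0.00937; adjusted p = 0.326 with an estimated correlation). Adjusted over the list alone, 18 glycolysis, 18 hypoxia, 17 cholesterol synthesis and 11 Notch pathway genes were lower.

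Neuronal and interferon response genes rose. Of 27 neuronal genes 16 rose and 4 fell between days 21 and 49, with STMN2 from 3.38 ± 0.842 to 12.8 ± 1.47 FPKM, while the neurofilament gene NEFM fell from 75.7 ± 7.59 to 15.1 ± 3.14 FPKM (camera adjusted p = 2.98e-05; adjusted p = 0.326 with an estimated correlation). Of 20 interferon response genes 12 rose and 3 fell, with B2M, the light chain of MHC class I, from 6.98 ± 0.14 to 14.1 ± 0.697 FPKM (camera adjusted p = 7.6e-05; adjusted p = 0.326 with an estimated correlation). Of 16 Wnt target genes 8 rose and 1 fell, including the feedback inhibitors NOTUM and APCDD1, at 12.3 ± 2.15 and 21.2 ± 0.103 FPKM on day 49 (camera adjusted p = 0.000684; adjusted p = 0.201 with an estimated correlation). Inflammation genes were higher at day 35 than at day 21 in 10 of 15 cases, with the chemokine gene CCL2 at 0.595 ± 0.0927, 2.77 ± 0.138 and 1.35 ± 0.264 FPKM on the 3 days (day 35 camera adjusted p = 4.1e-07; adjusted p = 0.159 with an estimated correlation). Adjusted over the list alone, 18 neuronal, 12 interferon response and 9 Wnt target genes were higher at day 49 and 13 inflammation genes at day 35. In HOX groups 10 to 13, 3 of 4 genes rose between days 21 and 49, or 4 adjusted over the list alone (camera adjusted p = 0.00732; adjusted p = 0.326 with an estimated correlation).

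**Figure D2:**
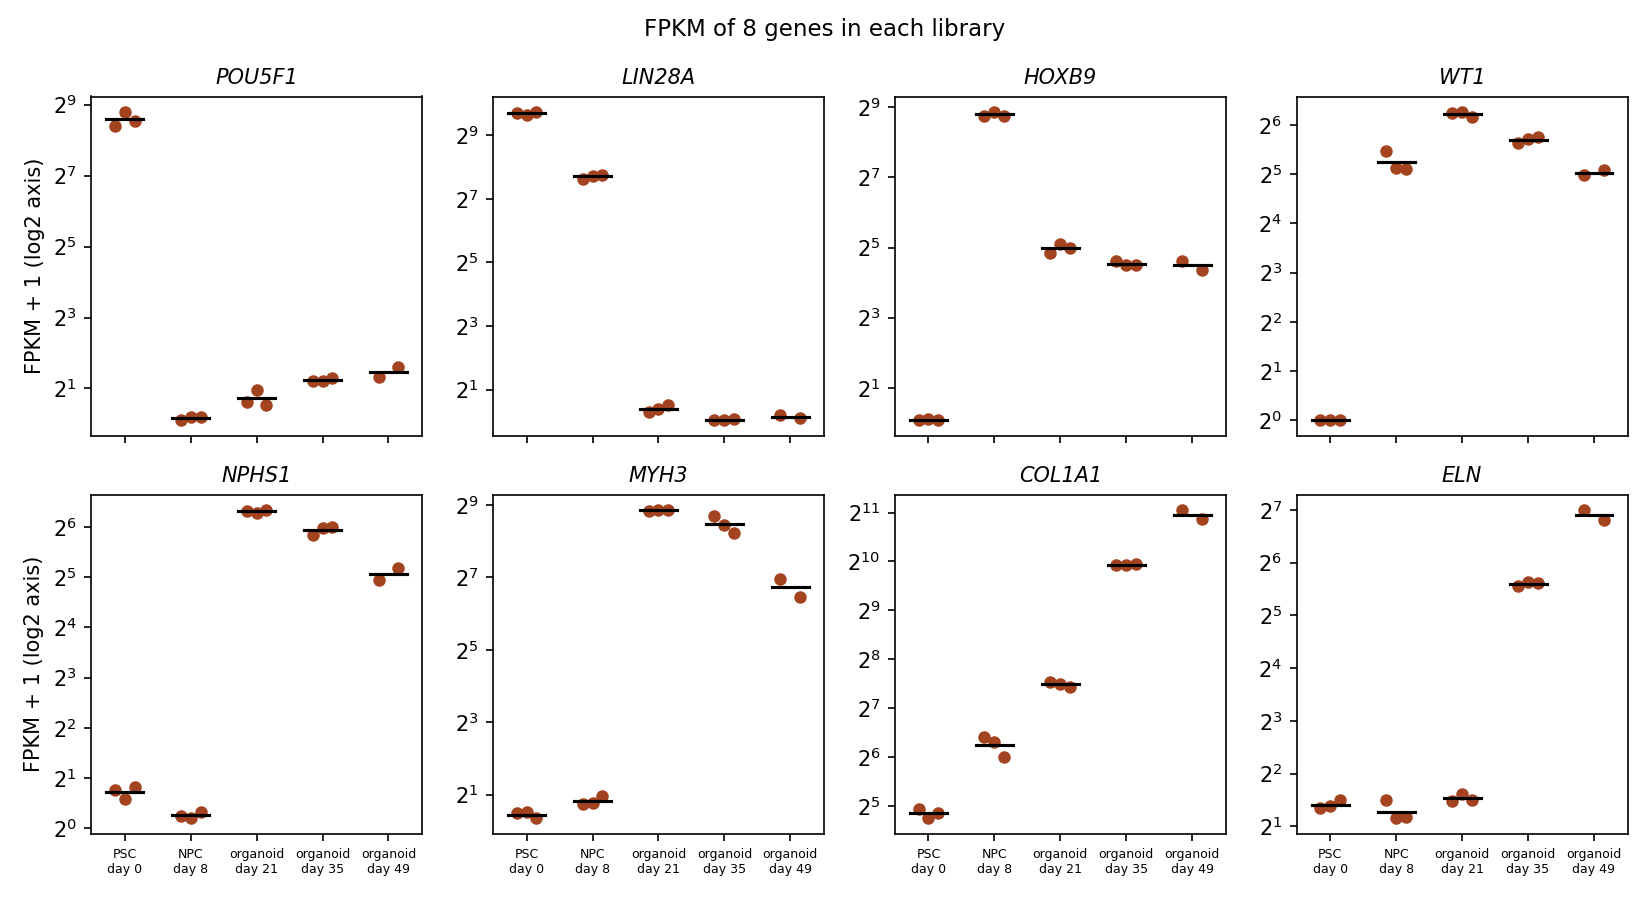
The vertical axes give FPKM + 1 on a log2 axis for 8 genes, and the horizontal axes the 5 stages; points are the 14 libraries and lines the stage means. COL1A1 and ELN are highest at day 49, and NPHS1 and MYH3 at day 21.

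Of 18976 genes tested over the 3 organoid days, 2756 were higher and 4119 lower at day 49 than at day 21, of which 605 and 515 changed at least 2-fold. Without the day 49 library numbered 3, 1835 genes were higher at day 49 than at day 21. From day 21 to day 35, 2205 were higher and 3039 lower. From day 35 to day 49, 701 were higher and 1009 lower, which leaving out 1 library moved to as few as 260 and 409, and edgeR gave 1404 higher and 1283 lower. The excess of falls depends on the scaling: median-of-ratios scaling gave 3209 higher and 3342 lower for day 49 against day 21, 2494 and 2491 for day 35 against day 21, and 782 and 846 for day 49 against day 35. With edgeR on reads worked back, 3858 were higher and 3588 lower for day 49 against day 21, and 3187 and 2850 for day 35 against day 21. No list compared between organoid days passed with an estimated correlation. The 10 most abundant genes took 8.97% and 9.44% of reads in the day 49 libraries, against 5.39% to 7.39% in those of days 21 and 35.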

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

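The fits with edgeR, DESeq2 and limma-voom on reads worked back, the replicate block, the single fit over all columns and the use of raw counts as FPKM were chosen after the table was seen. Where a setting changed a count, the cause was not tested unless stated. With an estimated correlation, 0 lists were higher and 0 lower for NPC against PSC, for day 35 against day 21, for day 49 against day 21 and for day 49 against day 35, in place of 9 and 12, 15 and 4, 13 and 7, and 12 and 7. For organoids against NPC it left 8 lists higher and 4 lower of 22 and 7. With fry, 19 lists were higher and 20 lower for NPC against PSC, 9 lower for day 35 against day 21, and 21 higher and 13 lower for day 49 against day 21. A mean of at least 5 FPKM leaves fewer genes to test by construction. It gave 3044 genes higher, 3076 lower and 7 lists lower for NPC against PSC, and 2801 genes higher, 3424 lower and 13 lists higher for organoids against NPC. For day 35 against day 21 it gave 1320 genes higher and 1 list lower, and for day 49 against day 21, 1495 genes higher and 4 lists lower. The neuronal list for day 49 against day 35 reversed under it, with a median log2 change of -0.26 (camera adjusted p = 0.264). Taking the raw counts of PSC column 3 as FPKM, which is a wrong unit, gave 0 genes higher, 0 lower and 6 lists lower for NPC against PSC. The results that reversed under it, each as a log2 change, were IGF2BP1: NPC against PSC (-2.14), CENPF: NPC against PSC (-1.69), B2M: NPC against PSC (-1.08), ACTN3: NPC against PSC (-0.40), COL1A1: NPC against PSC (-1.003), KDR: NPC against PSC (-0.13), HMGA2: NPC against PSC (-0.57) and APCDD1: NPC against PSC (-0.49). For day 49 against day 35, where 701 genes were higher and 1009 lower, edgeR gave 1404 higher, DESeq2 1216 and limma-voom 1424. The replicate block gave 457 higher and 640 lower there. Libraries with the same number did not deviate together, with correlations from -0.08 to 0.075 over 26 pairs. No pairing by number was seen, which does not exclude a shared culture or batch.

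Leaving out each library in turn gave 1835 to 2853 genes higher for day 49 against day 21, against 2756, with the lowest without day 49 replicate 3. For day 49 against day 35 it gave 260 to 579 higher and 409 to 839 lower. The lowest values there were without day 49 replicate 3, followed by 414 and 589 without day 49 replicate 2, and 467 and 657 without day 35 replicate 2. The counts of that comparison therefore depend on single libraries, and day 49 has only 2. Not run were the comparison of suspension with static culture, the difference between the systems over time, and the fits without a day block or a system block, as no column could be tied to suspension culture. A prior count of 0.5 and plain library size apply to counts only and were not run.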

Other observations

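The tests of explanations for the muscle, podocyte and POU5F1 patterns were chosen after the results were seen. So were the genes of the next paragraph. The median-of-ratios scaling was planned, and the splits of the libraries were set before their results were seen. The gene tests of NPC against PSC, organoids against NPC and day 49 against day 35 were not in the plan.

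The genes given here are known from early embryonic cells and were picked because they were lower in organoids than at NPC, so they do not show how many such genes fell. LIN28A, whose protein blocks maturation of the let-7 microRNAs, went from 829 ± 30.6 FPKM in PSC to 208 ± 9.27 at NPC, and was between 0.0349 and 0.32 FPKM on average in the organoids. Its relative LIN28B stood at 43.8 ± 2.67 in PSC and 47.3 ± 5.59 at NPC, a difference that did not pass (limma adjusted p = 0.326), and went from 5.92 ± 0.181 at day 21 to 0.298 ± 0.0306 FPKM at day 49, a log2 change of -2.41 with an SE of 0.095 (limma adjusted p = 2.46e-06). HMGA2, a chromatin protein gene, rose from 19.9 ± 1.00 in PSC to 84.9 ± 4.38 at NPC and fell to 46.1 ± 0.651 at day 21 and 12.7 ± 1.5 FPKM at day 49. IGF2BP1, which encodes an RNA-binding protein, went from 111 ± 6.21 at NPC to 42.3 ± 1.12 at day 21 and 16.8 ± 0.157 FPKM at day 49. IGDCC3 rose from 12.3 ± 0.0279 in PSC to 249 ± 15.9 at NPC and fell to 32.1 ± 0.247 and 3.75 ± 0.214 FPKM, and TRIM71, NR6A1, ARID3B and IGF2BP3 were also lower in organoids than at NPC and lower at day 49 than at day 21.

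Muscle genes rose in every organoid library relative to NPC. Reads carried over into single libraries are argued against, because the summed muscle FPKM differed by at most 1.413 times between libraries of 1 day. Adult muscle RNA from outside the culture is argued against too, because the adult myosins MYH1, MYH2 and MYH4 together reached at most 0.174% of MYH3. Muscle precursors already present at the NPC stage are a candidate source only. Of 6 paraxial mesoderm and somite genes 5 were higher at NPC than in PSC, and MESP2 was not tested. Among all 15981 tested genes 6823 were higher, so this count alone says little. At NPC MEOX1 stood at 51.0, TCF15 at 19.46, PAX3 at 13.55, MEOX2 at 2.98 and TBX6 at 1.93 FPKM. Which cells expressed the muscle genes stays open, since these are bulk libraries.

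The fall of podocyte genes from day 21 to day 49 could come from a few genes taking more of the reads, but their median log2 change was -0.48 before and -0.417 after median-of-ratios scaling. On dilution of all nephron cells alike, 15 of the 65 tested podocyte and proximal tubule genes rose, and 15 after that scaling. Among all 18976 tested genes 2756 were higher at day 49. Genes that rose may be expressed by other cells, so this count cannot decide on dilution, which stays open. A permutation test of the medians of both lists was run first, and its margin was narrow (two-sided p = 0.0456 over 33 and 32 genes that are not independent, 100000 resamples). On an equal loss of every podocyte gene, 6 rose, among them COL4A3, COL4A4 and TRPC6. The SD of the log2 changes of all 33 tested genes was 12.345 times their median SE. The scale used understates the change of low genes, so an equal loss would also give unequal changes. The SE measures only the spread between columns, which may be technical. Some of the genes that rose may be expressed by other cells too. These values therefore cannot decide on an equal loss, which stays open. A smaller share of podocytes together with changes within them stays open.

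POU5F1, near 0 at NPC, stood at 0.648, 1.36 and 1.76 FPKM on days 21, 35 and 49. Pluripotent cells as the only source of these reads are argued against. If all POU5F1 at day 49, 0.458% of the PSC level, came from them, 129.5 reads of NANOG, TDGF1, PRDM14 and ESRG would be needed. In the day 49 libraries 4 were seen (95% exact Poisson interval 1.09 to 10.24, counting error only). A smaller number of pluripotent cells is not excluded. Reads of the POU5F1 copies may contribute, as their summed reads, scaled to library size, at day 49 were 1.335 times those at NPC, with 2.48 CPM at NPC and 1.67 at day 21 for all copies, but 0.149, 0.441, 0.927 and 1.01 CPM from NPC to day 49 for POU5F1B alone. PSORS1C3, at chromosome 6, 31173735 to 31177899, lies within POU5F1 on the same strand and was 13.736 times its NPC level at day 49, though it went from 2.30 FPKM at day 35 to 1.41 at day 49 while POU5F1 did not fall. These last 2 explanations cannot be told apart, because the table does not say where in a gene the reads lie.

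Other splits of the libraries were also fitted. For organoids against NPC, fitted as 2 groups, 100 of the 165 possible splits were run. The real one alone gave 9418 genes or more, and the highest other gave 5. Splits that divide the columns of a stage add to the spread within groups, so this outcome says little about chance. The columns of a stage belong to 1 sample and may be repeat libraries, so chance differences between cultures are not excluded. For NPC against PSC the real split gave 11635 genes and the highest of the others 0, and for day 35 against day 21 these were 5088 and 0. With 10 splits each, these designs are too small for a share under 0.05, the real split being 1 of 10.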
